A study of Mus musculus with 14 samples.

How the data were processed

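Expression was measured in 14 RNA samples from mice, 6 of liver sinusoidal endothelial cells (LSEC), 4 of lung endothelial cells and 4 of thymus cells, each on 1 Mouse Genome 430 2.0 array of Affymetrix. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns, reverse transcribed from an oligo-dT primer, and transcribed in vitro into biotin-labelled cRNA. The deposited table holds 1 value per probe set and array for 45101 probe sets. The deposited values lie between 0 and 13.8 and were read as log2; the log base is not stated and was inferred from the range of the scanner. The authors' summarization, background correction and normalization are not given in the sources used here. Between 223 and 312 values per array stand at exactly 0, so the authors' processing put a floor there.

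The array medians of the deposited values spread over 0.282, more than the limit of 0.2 set before the data were examined, so all arrays were quantile normalized in limma. The models, thresholds, gene lists, the rule for named genes and all alternatives but 2 were also chosen before the data were examined. The 2 alternatives chosen after seeing the data were the values as deposited and a replicate block with the lung numbers crossed.

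Probe sets were named from the annotation table supplied for the array and the mouse gene table of assembly GRCm38.p6, which was used for names and for which genes neighbour each other. Of 45101 probe sets, 64 were array controls, 34958 carried 1 gene symbol, 932 several and 9211 none, and 34754 of those with 1 symbol matched a gene identifier. A gene was represented by its brightest probe set with 1 symbol. Of 18193 such genes, 13034 were tested, those whose highest tissue mean reached 6.87, the 40th percentile over probe sets. Genes absent from the annotation were not analysed here.

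Groups were control (without MxCre) and Cre+ (with MxCre) within each tissue. One linear model with 6 group means was fitted to all 14 arrays with limma 3.58.1 (lmFit and eBayes, trend and robust off) in R 4.3.3, with 8 residual and 3.21 prior degrees of freedom. The contrasts were Cre+ against control in each tissue, the differences of these effects between tissues, and control LSEC against control lung endothelial cells. P-values were adjusted by Benjamini-Hochberg within each contrast over the genes tested, at a threshold of 0.05. Log2 fold changes are Cre+ minus control, and fold differences are their antilogs. The 9 FoxO probe sets were tested in 3 tissues and adjusted over these 27 tests. The adjusted p-values in the text are from limma, whose spread estimate is shared by all groups.

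The 38 gene lists covered FoxO targets, signalling, growth and stress pathways, endothelial programmes, cell handling, markers of endothelial beds and of other cell types, and thymocyte stages. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 38 lists, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance without comparing them with other genes. Counts of passing members were taken over all genes tested and adjusted over the list alone. Lists of mast cell genes, Gimap genes and class 3 semaphorins were written after the results were seen.

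Overlap between tissues was tested with Fisher's exact test against independent lists. The genes named were the FoxO genes, Spry2, Klf2 and Cdkn1b, the 12 largest rises and falls among passing genes whose groups did not overlap, up to 4 passing members of each list with the largest change or the 2 with the smallest p where fewer passed, the 6 largest differences between tissues in each direction, and the 8 genes with the largest change among those called in several tissues. Values not needed for a comparison were left out of the text.

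The test was checked on simulated data with the same design, 13034 genes and 200 changed genes. Of simulated log2 changes of 0.5, 1 and 2 it recovered 59.7%, 83.6% and 97.0% in LSEC, 22.4%, 80.6% and 98.5% in lung endothelial cells and 34.3%, 77.6% and 95.5% in thymus. False calls were 4.76%, 5.63% and 1.43% of all calls. The simulated noise was independent for each gene and had 1 spread per gene in all 6 groups, as the fitted model assumes. On the real arrays genes vary together, and the median SD ran from 0.0752 in lung control to 0.132 in thymus Cre+ samples. The simulated rates therefore hold under the model alone and do not show the rates on the real data. For arrays, the number per group limits the precision; no depth is defined.

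Alternatives were median centring, the values as deposited, no filter and a stricter filter at the 60th percentile, the mean of all probe sets of a gene, eBayes with trend and robust on, array weights, only the arrays compared, a 2-fold limit, a replicate block, and leaving out each array in turn. Same-numbered control and Cre+ replicates were checked for pairing through the correlation of their deviations from the group means, which was -0.309, -0.0914 and -0.255 in LSEC, -0.235 in lung endothelial cells and 0.0522 in thymus, so the numbers were not used to pair samples in the tests reported. Samples could not be grouped by date or batch, which the labels do not give. The scan for samples far from their group needs 4 arrays in a group and was not run. Tests of overlap and permutation were run in R, and probe naming and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.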

Results

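RNA from 14 samples of mice with floxed alleles of 3 forkhead transcription factor genes was hybridised to Mouse Genome 430 2.0 arrays of Affymetrix, 1 array per sample. The labels write the alleles as Fk1, Fk2 and Afx, which are older names of Foxo1, Foxo3 and Foxo4, and give the genetic background as FVBn. Experimental samples carried MxCre, a Cre recombinase transgene under an interferon-inducible promoter, and are called Cre+ here. Control samples lacked the transgene. Liver sinusoidal endothelial cells (LSEC) made up 3 control and 3 Cre+ samples, lung endothelial cells 2 and 2, and thymus cells 2 and 2. The labels do not describe how Cre was induced, how the cells were isolated, or whether replicates came from separate animals, so the p-values measure the spread between samples. The deposited log2 values had array medians between 6.75 and 7.04, and between 223 and 312 of the 45101 probe sets per array stood at a floor of 0. After normalization, arrays of the same group correlated at r of 0.970 to 0.987 across the genes tested, and arrays of different tissues at 0.584 to 0.838. The number of arrays per group, 2 or 3, limits the precision of every comparison.

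The first question was whether the transcripts of the floxed genes were lower in Cre+ samples. Foxo1 RNA fell in LSEC on 3 of its 4 probe sets, most on 1416983_s_at, where the log2 level was 8.35 ± 0.31 (SD, n = 3) in control and 4.80 ± 0.57 (SD, n = 3) in Cre+ samples. Foxo4 RNA fell on probe set 1456753_at in every tissue, from 7.12 to 4.98 in LSEC, from 7.47 to 6.37 in lung endothelial cells and from 8.09 to 4.85 in thymus. Foxo3 RNA fell slightly in LSEC and rose in thymus, where probe set 1434832_at went from 8.92 ± 0.04 to 9.60 ± 0.10 (SD, n = 2 each). In LSEC the log2 fold changes of Foxo1 were -0.93, -2.10 and -3.56 on 1416981_at, 1416982_at and 1416983_s_at, with limma adjusted p of 0.000147, 2.48e-06 and 2.48e-06 over the 27 tests of 9 probe sets in 3 tissues. The same 3 probe sets gave -0.51, -1.06 and -1.29 in lung endothelial cells (adjusted p = 0.0152, 0.000849 and 0.00648) and -1.19, -1.02 and -1.80 in thymus (adjusted p = 0.000126, 0.000944 and 0.000912). The fourth, 1456529_at, was near background in LSEC, with a control level of 2.70 ± 2.70, and passed the test in no tissue (adjusted p = 0.165, 0.837 and 0.708). For Foxo4, 1456753_at gave -2.15 in LSEC, -1.10 in lung endothelial cells and -3.24 in thymus (adjusted p = 1.69e-05, 0.00464 and 3.45e-06). Its second probe set, 1422149_at, gave -0.10, -0.61 and -0.07, and passed in lung endothelial cells alone (adjusted p = 0.708, 0.0431 and 0.837). For Foxo3, 1434832_at gave -0.53, 0.10 and 0.68 in LSEC, lung endothelial cells and thymus (adjusted p = 0.000496, 0.462 and 0.000384). Probe set 1434831_a_at gave -0.58, 0.30 and 0.46 (adjusted p = 0.000974, 0.0777 and 0.0144), and 1450236_at passed in no tissue (adjusted p = 0.103, 0.965 and 0.936). No Foxo3 probe set fell in lung endothelial cells or thymus, so loss of all 3 floxed genes is not shown in these tissues. Where the Cre+ level lies under 6.87, the limit of the filter on dim probe sets, the size of a fall is uncertain: for Foxo4 on both probe sets, Foxo1 1416982_at in LSEC and Foxo1 1416983_s_at in LSEC and thymus. The files do not place the probe sets relative to the deleted exons, and a probe set outside the deleted part says nothing about recombination.

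**Figure D1:**
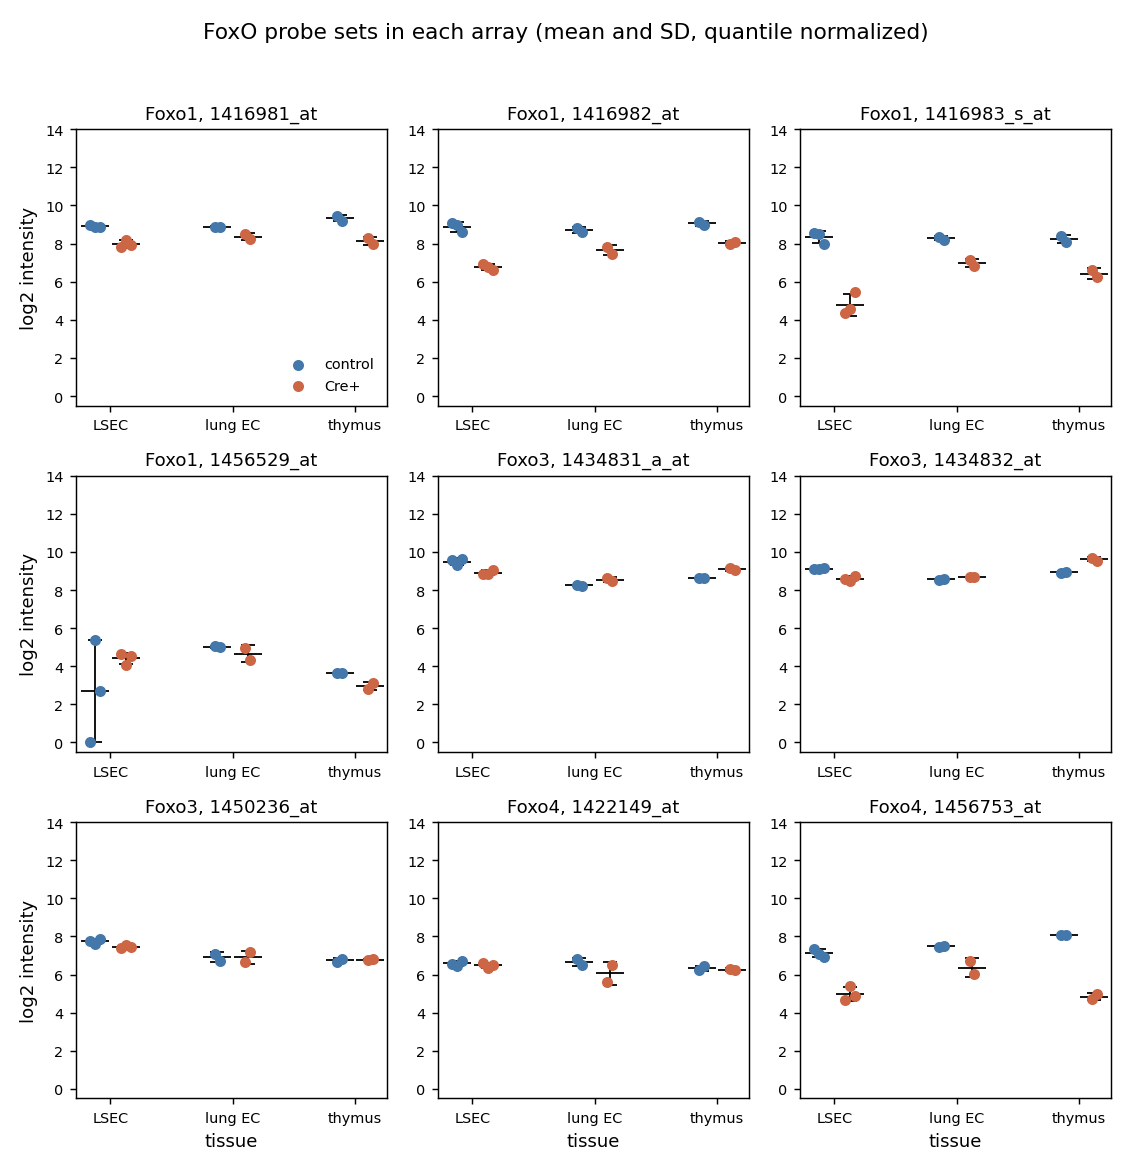
Log2 intensity of the 9 Foxo1, Foxo3 and Foxo4 probe sets by tissue, after quantile normalization. Points are arrays, and the horizontal line and bar are the mean and SD of a group. Foxo1 1416983_s_at fell from 8.35 to 4.80 in LSEC and Foxo4 1456753_at from 8.09 to 4.85 in thymus, while Foxo3 1434832_at rose from 8.92 to 9.60 in thymus.

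The LSEC comparison asked which transcripts differ between Cre+ and control liver sinusoidal endothelium. Angpt2, which encodes the Tie2 ligand angiopoietin 2, had the largest fall among the genes that passed: its log2 level was 11.64 ± 0.34 (SD, n = 3) in control and 7.80 ± 0.18 (SD, n = 3) in Cre+ LSEC, a 14.3-fold difference. Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, fell by 3.45 on the log2 scale, from 11.83 ± 0.21 to 8.38 ± 0.33. Il6, the gene of the cytokine interleukin 6, rose from 4.33 ± 0.15 to 8.25 ± 0.64. Vwf, which encodes the platelet-tethering von Willebrand factor, rose from 5.98 ± 0.21 to 9.24 ± 0.62. Among the other large falls were the flavin monooxygenase gene Fmo1 (log2 fold change -3.47), Esm1 (-3.46), which encodes the tip cell proteoglycan endocan, and Sema3d (-3.16), which encodes a secreted guidance cue. Abcc9 (-3.06) and Kcnj8 (-2.47), which encode the subunits of an ATP-sensitive potassium channel, both fell. The pyruvate dehydrogenase kinase gene Pdk4 (-2.92), the transporter gene Slc10a6 (-2.73), the cytochrome P450 gene Cyp4b1 (-2.72), the deoxyribonuclease gene Dnase1l3 (-2.50) and the secreted Wnt antagonist gene Frzb (-2.47) fell as well. Tpsab1, a mast cell tryptase gene, rose by 3.50, S100a8, a neutrophil calgranulin gene, by 2.91, the histidine decarboxylase gene Hdc by 2.59 and Cpa3, a mast cell carboxypeptidase gene, by 2.42. Other large rises were S1pr3 (2.50), a sphingosine 1-phosphate receptor gene, Gsta4 (2.36), Plac8 (2.27), Lrg1 (2.15), Magea4 (2.09) and Foxc2 (2.22), a forkhead gene of lymphatic and valve development. The lower of the 2 group levels lies under 6.87, the limit of the filter on dim probe sets, for all LSEC rises named in this paragraph but Plac8 and for the falls of Fmo1, Sema3d, Abcc9, Kcnj8, Slc10a6 and Frzb, so the sizes of these changes are uncertain. The same holds for the LSEC values of Sparcl1, Nid2, Adamts4, Gbp3, Cxcl10, Cdc6, Mfng, Nqo1, Hoxb5, Pdgfra, Prss16 and H2-Ab1. In limma, 790 of 13034 genes passed at an adjusted p threshold of 0.05, 366 higher and 424 lower in Cre+ LSEC, and 199 of them differed more than 2-fold. Adjusted p was 2.83e-06 for Angpt2, 5.17e-06 for Lyve1, 0.000507 for Il6 and 0.000177 for Vwf, and ranged up to 0.0433, for S100a8, among the other genes just named. In 788 of the 790 genes the control and Cre+ arrays did not overlap; over all genes tested, 23.7% did not overlap, where chance gives 10%. Without control replicate 2 the count was 500.

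FoxO target genes of cell cycle arrest, apoptosis and stress resistance were lower in Cre+ LSEC. Of 32 tested, 12 fell and 1 rose, with a median log2 fold change of -0.27 (camera adjusted p = 1.68e-06; adjusted p = 0.0868 with an estimated correlation). Gadd45a, a growth arrest and DNA damage gene, fell (-2.33), as did Depp1 (-1.65), an autophagy regulator gene, and Cdkn1b (-0.58), which encodes the cell cycle inhibitor p27, while the mitochondrial superoxide dismutase gene Sod2 rose by 0.68. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, fell by 1.47 (adjusted p = 7.6e-05), and Klf2, a flow-induced transcription factor gene, stood 0.70 higher without passing (adjusted p = 0.0599). The second probe sets of Spry2 (1421656_at) and Cdkn1b (1419497_at) gave -0.08 and -0.10. Both had levels under 6.87 in both groups. Genes that mark LSEC themselves fell: 14 of 17 were lower and none higher, with a median of -1.23 (camera adjusted p = 4.4e-17; adjusted p = 0.0868 with an estimated correlation), among them Fcgr2b (-2.21), an Fc receptor gene, Rspo3 (-2.12), which encodes a Wnt agonist, and Clec4g (-1.62), which encodes a lectin. The mean level of this list by array was 10.26, 10.59 and 10.24 in control and 9.08, 8.61 and 9.30 in Cre+ LSEC. Angiogenic sprouting genes showed 7 falls and 1 rise, of Mcam (2.01), among 21, with a median of -0.33 (camera adjusted p = 3.58e-05; adjusted p = 0.0868 with an estimated correlation). Extracellular matrix genes showed 5 falls among 27, of Nid2 (-1.82), Sparcl1 (-1.31), Ccn2 (-1.11), Lama4 (-0.99) and Adamts4 (-0.64), and 1 rise, of Lamc1 (0.58), with a median of -0.18 (camera adjusted p = 0.0229; adjusted p = 0.0868 with an estimated correlation). Interferon response genes showed 3 falls among 21, of Gbp3 (-1.49), Cxcl10 (-0.88) and Oasl1 (-0.49), with a median of -0.30 (camera adjusted p = 4.61e-05; adjusted p = 0.487 with an estimated correlation). Immediate early and heat shock genes, which respond to cell handling, moved with genotype too: 9 of 20 fell, among them Egr1 (-1.76) and Atf3 (-1.59), with a median of -0.53 (camera adjusted p = 7.64e-08; adjusted p = 0.0868 with an estimated correlation). Of 18 autophagy genes only Gabarapl1 (-0.49) passed, and the list median was -0.12 (camera adjusted p = 0.0457; adjusted p = 0.487 with an estimated correlation). Adjusted over the list alone, the falls and rises were 16 and 3 for FoxO targets, 15 and 0 for LSEC markers, 9 and 1 for sprouting, 8 and 2 for matrix, 8 and 1 for interferon, 12 and 0 for handling and 1 and 0 for autophagy. Camera with its preset correlation thus called 7 of 38 lists, all lower. With an estimated correlation it called 0, the smallest adjusted p being 0.0868, and the rotation test fry called 11. Of the 7, fry did not call interferon and autophagy (adjusted p = 0.0689 for both). It also called feedback inhibitors and Notch (adjusted p = 0.0235 for both) and natural killer, dendritic and mature thymocyte genes (adjusted p = 0.0315 each) lower, and lung endothelial markers higher (adjusted p = 0.0309). The median of each of the 7 lists was below 0 under all 3 scalings run, but the autophagy call was lost on the values as deposited.

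Of 34 proliferation genes 7 rose in LSEC, 6 of them genes of the replicative MCM helicase and the other its loading factor gene Cdc6, with log2 fold changes of 0.71 for Mcm2, 0.61 for Mcm4, 0.79 for Mcm5 and 0.91 for Cdc6. The list as a whole did not pass (8 higher adjusted over the list alone, median 0.13, camera adjusted p = 0.0808). Bone morphogenetic protein ligand genes Bmp4 (-1.88) and Bmp2 (-1.60) and the co-receptor gene Tgfbr3 (-0.78) fell, and Bmper (1.82), which encodes a modulator of those ligands, rose with Id1 (0.68), Tgfb2 (0.66) and Acvrl1 (0.65), within 4 rises and 3 falls of 22 TGF-beta and BMP genes (adjusted p = 0.778). In the Wnt list of 16, the receptor genes Fzd4 (0.50) and Fzd6 (0.38) rose, and 3 fell: Rspo3, Tcf4 (-0.73) and the ligand gene Wnt2 (-0.93) (adjusted p = 0.506). Tcf4 encodes a basic helix-loop-helix factor and is not the Wnt effector gene Tcf7l2, whose product shares that name. The Notch ligand gene Jag1 rose by 1.01 and Mfng, a glycosyltransferase gene of the same pathway, fell by 1.25, 2 of 17 members (adjusted p = 0.258). Nos3 (1.17), which encodes endothelial nitric oxide synthase, and Plat (1.79), a plasminogen activator gene, rose and Klf6 (-0.59) fell among 14 flow responsive genes (adjusted p = 0.963). Of 17 activation and cytokine genes 2 rose, Il6 and Tnfaip3 (0.47), and 3 fell: the adhesion receptor genes Vcam1 (-1.06) and Icam1 (-0.55) and the chemokine gene Ccl2 (-0.97) (adjusted p = 0.371). Among 22 antioxidant genes, Nqo1 (1.48) and Sod2 rose and Gpx3 (-2.21) and Sesn1 (-0.62) fell (adjusted p = 0.696). Errfi1 (-1.37) and Dusp5 (-0.84) fell with Spry2 among 15 feedback inhibitors of receptor tyrosine kinases, whose mean was -0.19 and median 0.01 (adjusted p = 0.235). Single passing members stood in the lists of PBX, MEIS and HOX factors (Hoxb5, -1.79, 1 of 13, adjusted p = 0.586) and of apoptosis (Fas, -0.60, 1 of 22, adjusted p = 0.963), and the insulin and PI3K list held a fall of Insr (-0.51) and a rise of Igfbp3 (1.47) among 21 (adjusted p = 0.555). None of 11 lymphocyte FoxO targets passed (1 higher and 1 lower adjusted over the list alone, median -0.17, adjusted p = 0.205). The PBX, insulin, flow, feedback inhibitor, apoptosis and antioxidant lists had members that went both ways, and their counts adjusted over the list alone were 2 higher and 1 lower, 1 and 1, 4 and 2, 0 and 3, 1 and 2, and 3 and 4. Median and mean differed in sign for all of these but the insulin list: 0.09 and -0.05 for PBX, -0.12 and 0.15 for flow, 0.01 and -0.19 for feedback inhibitors, 0.01 and -0.02 for apoptosis and 0.04 and -0.04 for antioxidant. For the BMP, Wnt, Notch and cytokine lists these counts were 4 and 4, 2 and 3, 1 and 2, and 2 and 4. Lamc1, Adamts4, Id1, Tgfb2, Acvrl1, Fzd6 and Tnfaip3 were named after their values were seen, to complete short counts, as was Pecam1 among the markers.

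Marker genes of other cells in Cre+ LSEC mostly did not pass. The pan-endothelial list had 4 falls, of Cldn5 (-1.42), a tight junction gene, Robo4 (-1.25), Sox18 (-1.04) and Pecam1 (-0.72), and the rise of Vwf among 20 members (median -0.17, adjusted p = 0.123). Of 14 lung endothelial markers, Ednrb, an endothelin receptor gene, rose by 1.84, and the list had a median of -0.01 and a mean of 0.20 (adjusted p = 0.371). Passing members of other lists were the hepatocyte gene Ttr (0.54, 1 of 6), the macrophage gene Cd14 (-1.45, 1 of 16), the mesenchymal genes Col1a2 (-0.69) and Pdgfra (-0.62, 2 of 16), the neutrophil gene S100a8 (2.91, 1 of 5), the natural killer cell gene Klrd1 (-0.49, 1 of 6) and the dendritic cell gene H2-Ab1 (-0.75, 1 of 8). The thymic epithelial gene Prss16 (-1.08, 1 of 10), the early thymocyte genes Kit (-1.17) and Bcl11a (-0.69, 2 of 14), and the mature thymocyte genes Gimap6 (-1.48) and Gimap4 (-1.28, 2 of 10) also fell. No member passed among cholangiocyte, lung epithelial, B cell, T cell, erythroid, platelet, double positive thymocyte and regulatory T cell markers; in limma 10 of the 71 genes in these lists and that of lymphocyte FoxO targets had an unadjusted p under 0.05. Camera called none of the cell type and thymocyte lists other than the LSEC markers, with adjusted p between 0.092 and 0.963. The stellate, fibroblast and mural list (median -0.21) passed with median centring and on the values as deposited (adjusted p = 0.0492 and 0.0483).

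**Figure D2:**
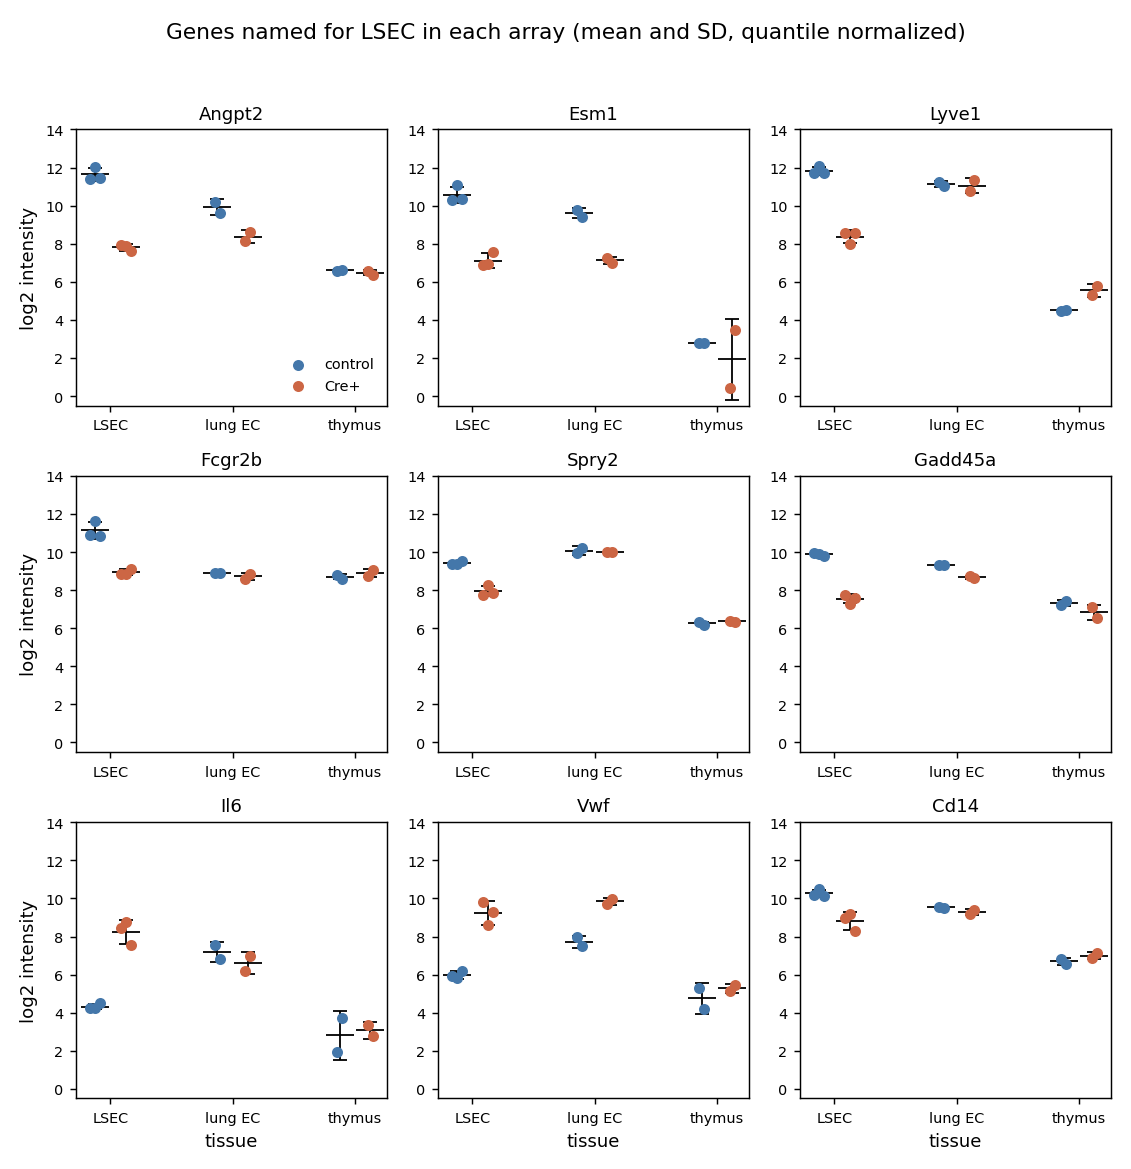
Log2 intensity of 9 genes named for LSEC, by tissue, after quantile normalization. Points are arrays, and the line and bar are the mean and SD of a group. In LSEC, Angpt2 fell from 11.64 to 7.80 and Lyve1 from 11.83 to 8.38, and Il6 rose from 4.33 to 8.25 and Vwf from 5.98 to 9.24.

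The lung comparison asked the same question in endothelial cell samples of another vascular bed. Control samples of this bed also held lung epithelial and collagen RNA, described below. Npy, which encodes neuropeptide Y, fell from 10.35 ± 0.18 to 7.16 ± 0.66 (SD, n = 2 each), 9.08-fold, and Aplnr, the apelin receptor gene of sprouting endothelium, fell from 8.62 to 6.20. The growth factor gene Pgf (-1.65), Bmp2 (-1.59), Cyp4b1 (-1.46), the potassium channel subunit gene Kcne3 (-1.42) and Gimap4 (-1.33), a gene of the GTPase of immunity-associated protein family, also fell. Cap1, which encodes an actin-binding cyclase-associated protein, rose from 7.90 ± 0.13 to 11.27 ± 0.07 (SD, n = 2 each). Ptprb, which encodes a phosphatase of the endothelial receptor Tie2, rose by 1.23, and Gm34303, a predicted gene, by 1.08. The other falls were C730049O14Rik (-1.16), the ubiquitin ligase gene Rnf125 (-1.12), the respiratory chain subunit gene Ndufs5 (-1.06) and the lipid phosphatase gene Plpp3 (-0.79). The lower group level of Aplnr, Pgf and Gm34303 lies under 6.87, so the sizes of these changes are uncertain. Limma passed these 14 genes of 13034, 3 higher and 11 lower, with adjusted p from 0.00115 for Npy and Gm34303 to 0.0475 for Plpp3. At an unadjusted p under 0.05 there were 595 genes, fewer than the 651.7 that chance gives. In all 14 the arrays of the groups did not overlap, as in 38.4% of all genes, where chance gives 33.3%. Angiogenic sprouting genes were lower as a group (median -0.28, camera adjusted p = 1.96e-11; adjusted p = 0.0209 with an estimated correlation), with Aplnr the 1 of 21 that passed and 8 lower adjusted over the list alone. Angpt2 gave a log2 fold change of -1.53 (adjusted p = 0.0514) and Vwf 2.11 (adjusted p = 0.121). Pan-endothelial markers were lower by camera (median -0.33, adjusted p = 3.06e-05; adjusted p = 0.519 with an estimated correlation), although the member that passed, Ptprb, rose; adjusted over the list alone 2 of 20 were higher and 4 lower. Extracellular matrix genes were lower (median -0.07, camera adjusted p = 0.0147; adjusted p = 0.124 with an estimated correlation) with 0 of 27 passing limma, 4 at an unadjusted p under 0.05, 2 lower adjusted over the list alone and a fry adjusted p of 0.092. FoxO targets of cell cycle and stress had 0 of 32 passing limma, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median -0.08, adjusted p = 0.0954, and 0.928 by fry); Gadd45a gave -0.63, Spry2 -0.09, Klf2 -0.04 and Cdkn1b -0.15. Macrophage and lung epithelial markers had medians of 0.25 and 0.09 and were not called (adjusted p = 0.227 and 0.654). Each lung array decided the gene count: it was 2 without control replicate 1, 4 without control replicate 2, 2 without Cre+ replicate 1 and 2 without Cre+ replicate 2. The 3 list calls became 5 without control replicate 2 or without Cre+ replicate 1.

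The thymus comparison asked which transcripts differ between Cre+ and control thymus cells. Epha2, which encodes an ephrin receptor tyrosine kinase, rose from 4.90 ± 0.27 to 9.31 ± 0.28 (SD, n = 2 each). Gm34303 rose from 6.73 ± 0.04 to 10.02 ± 0.04. H2-Eb1, which encodes a class II major histocompatibility chain, fell from 10.99 ± 0.20 to 8.18 ± 0.01, 7.01-fold, while H2-Ab1, another class II gene, gave 0.44 (adjusted p = 0.434). Foxo4 fell by 3.24. Other rises were the RNA-binding protein gene Rbm24 (1.92), Tesc (1.49), the lymphocyte surface gene Cd7 (1.35), the nuclear receptor gene Rora (1.28), Tspan9 (1.24), the VEGF receptor gene Flt1 (1.00), Tha1 (0.93), the matrix gene Sparc (0.81), Naaa (0.79) and Pax8 (0.79). Other falls were the proton-sensing receptor gene Gpr4 (-1.87), Gimap6 (-1.59), the tubulin gene Tubb2a (-1.57), the calcium channel gene Cacna1e (-1.49), Tmem71 (-1.27), the deubiquitinase gene Usp24 (-1.24), Foxo1 (-1.19), the T cell kinase gene Tec (-1.17), Cbwd1 (-1.15) and Pcmtd2 (-1.15). The lower group level lies under 6.87 for Epha2, Gm34303, Foxo4, Tesc, Flt1, Tha1, Gpr4, Cacna1e, Tmem71 and Cbwd1, so the sizes of these changes are uncertain. Limma passed 53 of 13034 genes, 22 higher and 31 lower, and 24 differed more than 2-fold. Adjusted p was 1.84e-06 for Epha2, 1.39e-08 for Gm34303, 0.000309 for H2-Eb1, and up to 0.0434 for Tha1. In all 53 the arrays of the groups did not overlap, as in 41.6% of all genes, where chance gives 33.3%. The 2 Cre+ arrays correlated at r = 0.970 with a median SD of 0.132, the 2 control arrays at 0.986 with 0.0766. Cre+ replicate 2 had a mean r of 0.968 with the other thymus arrays, which themselves had 0.976 to 0.979. A fit without Cre+ replicate 1 leaves it as the only Cre+ array. Proliferation genes were lower by camera (median -0.51, adjusted p = 7.82e-18; adjusted p = 0.285 with an estimated correlation): 32 of 34 stood below 0, 0 passed limma, 24 had an unadjusted p under 0.05, 12 were lower adjusted over the list alone, and fry gave an adjusted p of 0.0541. The ribonucleotide reductase gene Rrm1 gave -0.55 (adjusted p = 0.073) and Mcm3 -0.52 (adjusted p = 0.0696). Extracellular matrix genes were higher (median 0.31, camera adjusted p = 1.67e-07; adjusted p = 0.00745 with an estimated correlation), with Sparc the 1 of 27 that passed and 8 higher adjusted over the list alone. Stellate, fibroblast and mural cell markers moved with them (median 0.35, camera adjusted p = 0.0207; adjusted p = 0.391 with an estimated correlation), with Col3a1 (0.75) the 1 of 16 that passed, 1 adjusted over the list alone. Mature thymocyte genes were lower (median -0.32, camera adjusted p = 0.0207; adjusted p = 0.285 with an estimated correlation), with Gimap6 the 1 of 10 that passed and 1 higher and 3 lower adjusted over the list alone. Interferon response genes were higher (median 0.30, camera adjusted p = 0.0428; adjusted p = 0.571 with an estimated correlation) with 0 of 21 passing limma, 2 at an unadjusted p under 0.05, 0 adjusted over the list alone and a fry adjusted p of 0.365. Lymphocyte FoxO targets had 0 of 11 passing limma and 1 at an unadjusted p under 0.05 (median -0.09, camera adjusted p = 0.358, fry 0.599); Cdkn1b gave -0.59 (adjusted p = 0.124), Klf2 -0.34 and Spry2 0.12. Markers of double positive thymocytes and T cells had medians of -0.04 and 0.02 (adjusted p = 0.416 and 0.83). Dendritic, macrophage and thymic epithelial markers stood above 0 in 8 of 8, 14 of 16 and 9 of 10 members, with medians of 0.27, 0.27 and 0.25. Camera called none of these lists (adjusted p = 0.0939, 0.217 and 0.189), and fry called the dendritic list (adjusted p = 0.0491, 0.574 and 0.16). Hepatocyte, lung epithelial and LSEC markers also stood above 0 in 6 of 6, 10 of 12 and 14 of 17 members. Their medians were 0.33, 0.22 and 0.13, and camera did not call them (adjusted p = 0.189, 0.362 and 0.189). B cell markers had a median of -0.03. Values above 0 were thus not confined to cell types of the thymus. The gene count was 34 without control replicate 1, 15 without control replicate 2, 241 without Cre+ replicate 1 and 30 without Cre+ replicate 2, 34 with median centring and 28 on the values as deposited, and the 5 list calls became 3 without control replicate 2.

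**Figure D3:**
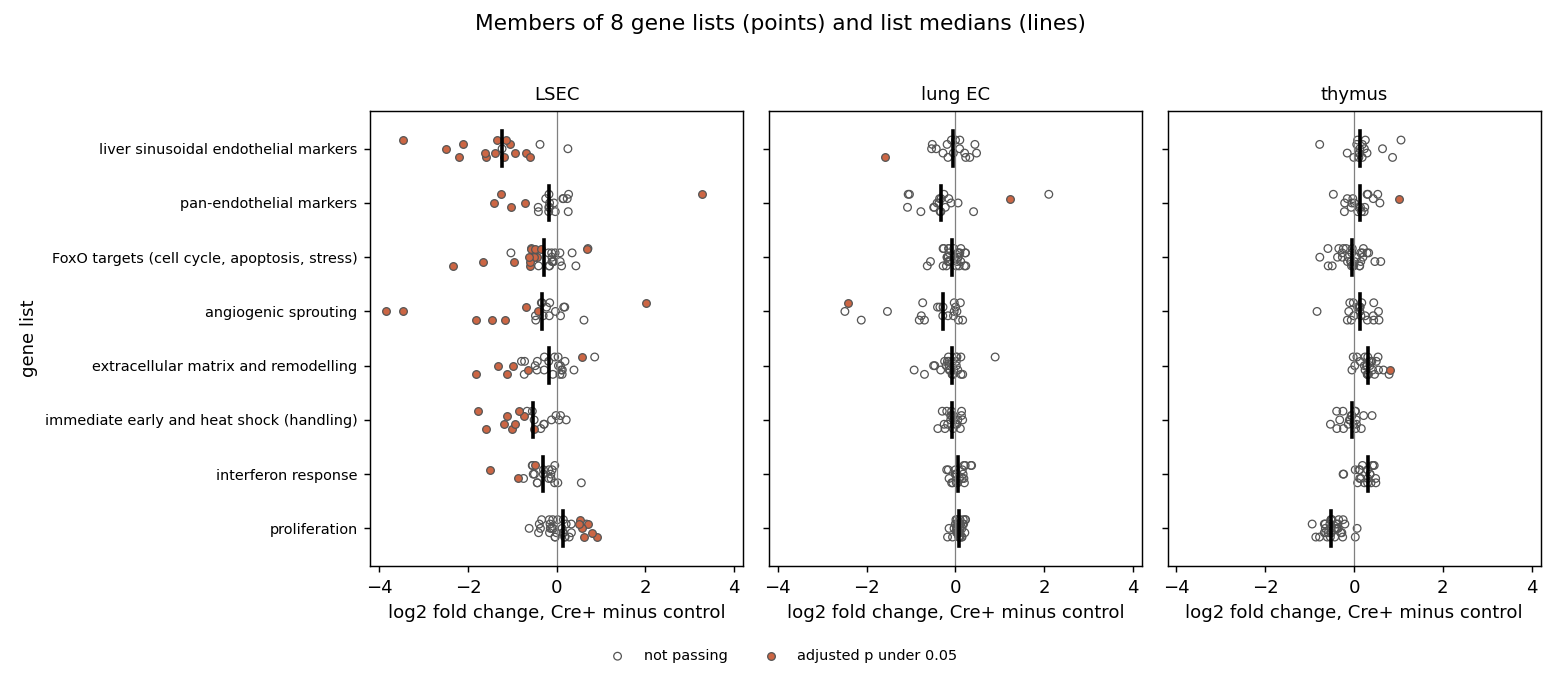
Log2 fold change, Cre+ against control, of the members of 8 gene lists in each tissue. Points are genes, filled where the adjusted p was under 0.05, and lines are list medians. The median of the LSEC markers was -1.23 in LSEC, that of proliferation genes -0.51 in thymus and that of sprouting genes -0.28 in lung endothelial cells, each below 0 under all 3 scalings.

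Genes that changed in more than 1 tissue were compared to ask whether the genotype acts on the same transcripts. Gm34303 rose in all 3 tissues, by 1.85, 1.08 and 3.28 in LSEC, lung endothelial cells and thymus. Cap1 rose in LSEC (2.01) and lung endothelial cells (3.37), and gave 2.15 in thymus without passing (adjusted p = 0.0696). Npy fell in LSEC (-1.33) and lung endothelial cells (-3.18), and gave 0.12 in thymus, where both levels lie under 6.87 and leave little signal to lose. Cyp4b1, Bmp2 and Gimap4 fell in both endothelia, Gimap4 with -1.05 in thymus (adjusted p = 0.0559). Gpr4 and Gimap6 fell in LSEC (-1.30 and -1.48) and thymus, and gave -0.91 and -0.35 in lung endothelial cells without passing. LSEC and lung endothelial cells shared 2 genes higher and 9 lower, where independent lists give 0.0842 and 0.358 (Fisher's exact test, one-sided, p = 0.00232 and 1.95e-12). LSEC and thymus shared 3 higher, Gm34303 and, named after their values were seen, Nav1 and Nfix, and 8 lower, among them the floxed genes Foxo1 and Foxo4, and Foxo3 went opposite ways. With the 3 floxed genes left out, 3 were shared higher and 6 lower, where chance gives 0.590 and 0.937 (Fisher's exact test, one-sided, p = 0.0201 and 0.000277). Lung endothelial cells and thymus shared 1 higher, Gm34303, where chance gives 0.00506 (Fisher's exact test, one-sided, p = 0.00506). They shared 0 lower, where chance gives 0.0262. All contrasts use the same spread estimate of a gene, and genes vary together, so the lists are not fully independent. The p-values of the overlaps are therefore a description only. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.183 (Spearman 0.0889) for LSEC and lung endothelial cells, 0.0104 (-0.0603) for LSEC and thymus and 0.118 (0.103) for lung endothelial cells and thymus. The 11 genes of LSEC and lung became 2 without any single lung array and 7 without LSEC control replicate 1, the 11 of LSEC and thymus 6, 5 and 20 without thymus control replicate 1, thymus control replicate 2 and thymus Cre+ replicate 1, and the 1 of lung and thymus 2 without thymus Cre+ replicate 2.

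**Figure D4:**
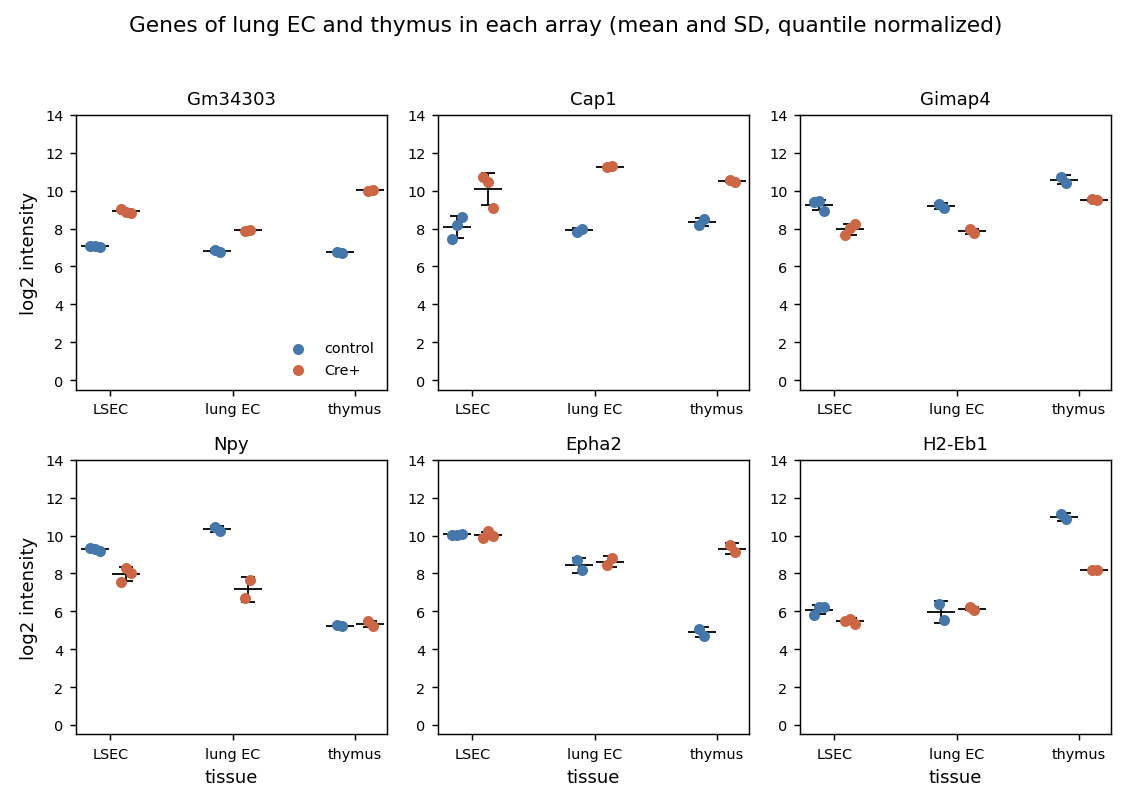
Log2 intensity of 6 genes named for several tissues or for thymus, after quantile normalization. Points are arrays, and the line and bar are the mean and SD of a group. Gm34303 was higher in Cre+ samples of all 3 tissues, by 1.85, 1.08 and 3.28, under every scaling run, and Epha2 rose from 4.90 to 9.31 in thymus.

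Tests of the difference between tissues asked whether the effect of genotype depends on the tissue. The fall of the floxed genes' RNA was not matched between tissues: Foxo1 1416983_s_at gave -3.56, -1.29 and -1.80 and Foxo4 1456753_at -2.15, -1.10 and -3.24 in LSEC, lung endothelial cells and thymus, and Foxo3 rose in thymus. The tests therefore do not separate tissue from the amount of loss. Nor do they separate tissue from the make-up of the samples. The mean level of the lung epithelial list was 9.72 in control lung samples and 6.90 in control LSEC. For the stellate, fibroblast and mural list these levels were 9.59 and 7.11, and for the pan-endothelial list 9.44 and 10.02. Lyve1 fell in LSEC and gave -0.09 in lung endothelial cells, a difference of -3.37 (adjusted p = 0.00218). Il6 rose in LSEC and gave -0.57 in lung endothelial cells, a difference of 4.50 (adjusted p = 0.0202). Epha2 rose in thymus and gave -0.03 in LSEC, a difference of -4.44 (adjusted p = 5.44e-05). In limma, 80 of 13034 genes differed between the LSEC and lung effects (37 more positive in LSEC and 43 more negative), 305 between LSEC and thymus (117 and 188) and 4 between lung endothelial cells and thymus (1 and 3). The LSEC and lung count was 5 and 29 without lung control replicates 1 and 2, 4 and 18 without lung Cre+ replicates 1 and 2, and 44, 33 and 48 without LSEC control replicates 1, 2 and 3. The LSEC and thymus count was 142 and 62 without thymus control replicates 1 and 2 and 666 and 92 without thymus Cre+ replicates 1 and 2, and the lung and thymus count was 7 without thymus control replicate 1, 21 and 7 without thymus Cre+ replicates 1 and 2.

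Control LSEC and control lung endothelial cells were compared to describe how the 2 preparations differ without Cre. Stab2, a scavenger receptor gene of sinusoidal endothelium, stood 5.71 higher in LSEC on the log2 scale, Dnase1l3 4.03, the transcription factor gene Gata4 3.22 and Clec4g 2.40. Lung samples had higher Ace (-2.01 as LSEC minus lung), the angiotensin-converting enzyme gene, and Car4 (-0.86), as well as the lung epithelial genes Scgb1a1 (-8.42) and Sftpc (-5.49) and the collagen genes Col1a1 (-6.48) and Col3a1 (-5.25). The lower level lies under 6.87 for Stab2, Dnase1l3, Gata4, Scgb1a1, Sftpc and Col1a1, so the sizes of these differences are uncertain. Of 17 LSEC markers 14 were higher in LSEC and 0 higher in lung, with a median difference of 2.16. Of 14 lung endothelial markers 8 were higher in lung and 3, Ednrb (1.79) among them, in LSEC (median -0.86). Pan-endothelial markers had 12 higher in LSEC and 4 higher in lung of 20 (median 0.84). Of 12 lung epithelial markers 10, and of 16 stellate, fibroblast and mural markers 11, were higher in the lung samples (medians -2.22 and -1.92). In limma 6015 of 13034 genes differed, 3384 higher in LSEC and 2631 higher in lung; on the values as deposited the balance turned, with 2555 higher in LSEC and 2960 higher in lung among 5515. Tissue and preparation cannot be separated in this comparison.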

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

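Of the tests in this part, those of scaling and of the flanking position for Gm34303, and those of endothelial share, other cell types and handling for the LSEC markers, were chosen after the result was seen.

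The results below concern effects of genotype that differ between tissues by a limma test of the difference, or probe sets outside the gene comparisons. In all, 80 genes differed between LSEC and lung endothelial cells, 305 between LSEC and thymus and 4 between lung endothelial cells and thymus. Between LSEC and lung, the LSEC effect was higher for Il6 by 4.50, Mcam by 2.75, Sema3g by 2.28, Plac8 by 2.19, Foxc2 by 2.18 and the tetraspanin gene Cd9 by 2.15. It was lower for Sema3d (-3.42), Lyve1 (-3.37), Fmo1 (-3.35), Pdk4 (-2.49), Angpt2 (-2.31) and Slc10a6 (-2.17). Between LSEC and thymus, the LSEC effect was higher for Il6 by 3.66, Hdc by 3.12, Vwf by 2.74, Magea4 by 2.47, Foxc2 by 2.35 and H2-Eb1 by 2.20. It was lower for Lyve1 (-4.51), Epha2 (-4.44), Fmo1 (-3.75), Angpt2 (-3.72), Abcc9 (-3.36) and Pdk4 (-3.33). Between lung endothelial cells and thymus, the differences were 2.99 for H2-Eb1, -4.21 for Epha2, -3.30 for Npy and -2.20 for Gm34303. Both group levels lie under 6.87, the limit of the filter on dim probe sets, for Lyve1, Angpt2, Abcc9, Pdk4 and Npy in thymus and for H2-Eb1 in LSEC and lung endothelial cells. These 5 genes in thymus and H2-Eb1 have little signal there to lose, so their differences do not separate a tissue-dependent effect from a low level. Both levels also lie under that limit for Il6, Hdc, Vwf and Foxc2 in thymus and for Sema3g and Magea4 in LSEC, and 1 level does for Il6, Hdc, Vwf, Foxc2, Sema3d, Fmo1, Slc10a6 and Abcc9 in LSEC, Il6 and Gm34303 in lung endothelial cells and Magea4, Epha2 and Gm34303 in thymus, so the sizes of these differences are uncertain. Leaving out lung Cre+ replicate 1 reduced the 80 genes to 4 and lung control replicate 1 to 5. The counts without lung control replicate 2 and lung Cre+ replicate 2 were 29 and 18, and without LSEC control replicates 1, 2 and 3 they were 44, 33 and 48. Leaving out thymus Cre+ replicate 1 raised the 305 to 666 and the 4 to 21. The 305 became 142 and 62 without thymus control replicates 1 and 2 and 92 without thymus Cre+ replicate 2, and the 4 became 7 without thymus control replicate 1 or thymus Cre+ replicate 2.

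Among 4284 probe sets with no single gene symbol, which no gene comparison used, 72 differed in LSEC (39 higher and 33 lower, 640 at an unadjusted p under 0.05) and 26 in thymus (12 and 14, 371 unadjusted) by limma. In lung endothelial cells limma called 0, with 218 at an unadjusted p under 0.05, where chance gives 214.2; no other tool was run on these probe sets.

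The 6 LSEC arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 790 genes and the highest other 11, so 1 of the 10 reached the real count. For the gene lists 2 of the 10 splits reached the real count, the real split calling 7 lists and the highest other also 7. Camera with its preset correlation called between 2 and 7 lists in every other split. Each of those splits has unequal numbers of control and Cre+ arrays on its sides, so part of any genotype effect remains. The splits therefore do not show how many list calls are false, and they give the list calls in LSEC no support.

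Gm34303, a predicted gene, was higher in Cre+ samples of all 3 tissues. Scaling between arrays is argued against, since its smallest log2 fold change over quantile normalization, median centring and the values as deposited was 1.08. A change over the whole region around Foxo1 is argued against as well, since the 10 nearest tested genes had a median absolute mean change of 0.0705, against 0.0732 for all genes, and none of them passed in any tissue. Altered transcription next to the recombined Foxo1 gene may account for it: Gm34303 is the next annotated gene to Foxo1, one of 6 tested genes that flank the 3 floxed genes, which are 0.0460 percent of all tested, and it ranked 1 by its smallest absolute t over the tissues. None of the other 5 passed as higher. Mgst2, on the other side of Foxo1, gave 0.19, 0.03 and -0.88 in LSEC, lung endothelial cells and thymus. Sesn1, next to Foxo3, gave -0.62, -0.01 and -0.77 and passed in LSEC alone. Sesn1 is also a member of the FoxO target list, so its fall does not bear on position. Afg1l, on the other side of Foxo3, gave 0.08, 0.06 and 0.16. Beside Foxo4, Snx12 gave 0.12, 0.01 and 0.09 and Gm614 0.06, -0.10 and -0.10. That remains a hypothesis, since the position was looked up after the rise was seen and the arrays do not show which transcript the probe set detects.

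LSEC markers were lower in Cre+ LSEC, with a median of -1.23. A smaller share of endothelial cells is argued against, since the pan-endothelial median lay 1.06 above that of the LSEC markers. By array the pan-endothelial mean was 10.02, 10.12 and 9.91 in control and 9.97, 9.75 and 10.02 in Cre+ LSEC. A permutation of genes between the 2 lists gave p = 0.00064. It treats genes as independent, although their estimated correlations were 0.44 and 0.24 within the LSEC marker and pan-endothelial lists. That p does not measure the spread between samples. More cells of other types as the cause are argued against by the same difference between the lists, since they would lower all endothelial genes alike. The medians of 11 lists of other cell types had a median of -0.0553, with 3 above 0, and that of mast cells was 0.35, so a rise in mast cells of itself stays open. A shift of the whole profile toward that of lung endothelium stays open. Over 12520 genes outside the lists the covariance of the LSEC effect with control lung minus control LSEC was 0.0476. In 100 simulations with no effect the shared control arrays gave 0.00949 to 0.0192, and the observed value exceeded their mean by 0.0335. The simulated noise was independent for each gene, while genes on real arrays vary together, so that range can be too narrow. The lung endothelial markers went both ways in LSEC, with a median of -0.01 and a mean of 0.20 (6 above 0 and 8 below, 4 higher and 1 lower at an unadjusted p under 0.05, adjusted p = 0.371 by camera and 0.0309 by fry, higher), which does not decide, and the lung epithelial and stellate, fibroblast and mural lists had medians of -0.14 and -0.21. The lung control samples also hold epithelial and collagen RNA, so this axis is not endothelium alone. A loss of LSEC identity and a larger share of endothelium from other liver vessels could both lower these markers and were not tested apart. A difference in handling stays open, since the handling genes had a median of -0.53. At equal handling level the mean of the LSEC markers differed by -2.15 between the groups (95% interval -4.06 to -0.24, linear model of the 6 arrays with 3 residual degrees of freedom). Within groups the slope of the marker mean on the handling level was -1.29 ± 0.93 (SE), where handling as the cause needs a positive one. The slope was below 0 in all 9 fits, but these reuse the same 6 arrays. Its 95% interval in the main fit, -4.24 to 1.66, includes positive slopes, so its sign is not settled. Handling levels did not overlap between the groups, at 9.94, 9.86 and 10.21 in control and 9.37, 9.47 and 9.34 in Cre+ LSEC. The difference at equal handling is therefore an extrapolation. The difference at equal handling was at least as large as the unadjusted -1.36 in each fit, -2.43 with median centring, -1.99 as deposited and -3.90 to -1.69 leaving out 1 array. Its interval nevertheless reached 0 on the values as deposited (-4.33 to 0.35) and without 5 of the 6 arrays in turn, where 2 residual degrees of freedom are left, so handling is not excluded.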

How the results depend on the processing

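The values as deposited and the block with crossed lung numbers were chosen after the data were seen; the other alternatives were chosen before. Of 195 gene effects and gene differences between tissues named in the text, 171 passed. None of these 171 changed direction under an alternative, except that Foxo1 in LSEC gave 1.73 on probe set 1456529_at, which is near background there. Other probe sets were taken singly for the FoxO genes alone. Values that did not pass and changed sign were Epha2 in LSEC (0.0056 as deposited, and -0.13 to 0.047 leaving out 1 array), Lyve1 (-0.37 to 0.19), Klf2 (-0.11 to 0.044) and Spry2 (-0.24 to 0.063) in lung endothelial cells and Npy in thymus (-0.0029 to 0.23), the last 4 leaving out 1 array. Of the gene results 8 lost the threshold with median centring and 8 as deposited, 50 with no filter, 74 with only the arrays compared, 46 with the 2-fold limit, 77 with the replicate block, 20 with the mean of all probe sets, 12 with array weights and 4 with trend and robust. The block with lung numbers crossed was run on the lung results alone, where 11 lost the threshold and 16 stayed on their side of it. Leaving out 1 array at a time kept 894 recomputed values on their side of the threshold and took 248 below it. Where an arm was left with 1 array, that array was assumed to vary like the other groups.

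With only the arrays compared, which leaves fewer degrees of freedom, the counts were 358 in LSEC, 4 in lung endothelial cells and 4 in thymus, 38 for LSEC against lung, 128 for LSEC against thymus, and 8 lists in thymus. Requiring more than 2-fold left, by construction, 199 genes in LSEC, 24 in thymus, 169 for LSEC against thymus and 1466 for control LSEC against lung. The replicate block, which uses degrees of freedom for numbers that do not pair the samples, gave 352 in LSEC, 0 in lung endothelial cells (limma, 466 at an unadjusted p under 0.05) and 3 with the numbers crossed, 10 in thymus, 1, 23 and 2 for the differences, 3124 for the controls, and 0, 6 and 0 shared genes. Without the filter on dim probe sets the counts were 2 in lung endothelial cells, 20 in thymus, 30 and 122 for LSEC against lung and thymus, and 2 and 6 shared by LSEC with lung and thymus. With the stricter filter they were 109 in thymus, 12 for lung against thymus, 5 lists in lung endothelial cells, and 25 and 3 shared by thymus with LSEC and lung. The mean of all probe sets gave 29 in thymus, 13 for lung against thymus, 6 lists in lung endothelial cells, and 7 and 2 shared by thymus with LSEC and lung. Trend and robust gave 116 in thymus, 131 for LSEC against lung and 20 for lung against thymus. Array weights gave 54 in lung endothelial cells, 32 in thymus, and 168, 193 and 7 for the differences. Median centring gave 34 genes in thymus and 7 shared by LSEC and thymus, and the values as deposited gave 28 and 7. With an estimated correlation camera called 0, 1 and 1 lists in LSEC, lung endothelial cells and thymus (7, 3 and 5 with the preset), and fry called 11 in LSEC and 1 in lung endothelial cells. For the filter, probe set, variance, weight and scaling alternatives the cause was not tested.

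Leaving out 1 array gave 500 to 623 genes in LSEC, 2 to 4 in lung endothelial cells and 15 to 241 in thymus, with 453 to 519 of the 790 LSEC calls and 2 of the 14 lung calls kept. It gave 4 to 98, 62 to 666 and 3 to 21 for the differences of LSEC with lung, LSEC with thymus and lung with thymus, and 4176 to 5659 for the controls. It gave 7 to 10, 2 to 5 and 3 to 5 lists, and 2 to 12, 5 to 20 and 1 to 2 shared genes. Without thymus Cre+ replicate 1 the counts were 241, 666 and 21, and without lung Cre+ replicate 1 that of LSEC against lung was 4; the cause was not tested. Signal over background limits Foxo1 1456529_at and other dim probe sets: between 223 and 312 values per array stand at the floor.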

Other observations

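The tests in this part concern patterns and gene families that were chosen after the results were seen. For the mast cell test alone the deciding outcome was set before it was run, on a list written after the mast cell rises were seen.

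Genes of the GTPase of immunity-associated protein family, which regulate lymphocyte survival, had medians below 0 in all 3 tissues, over 8 members -0.31 in LSEC, -0.32 in lung endothelial cells and -0.39 in thymus. The medians were -0.32, -0.35 and -0.38 with median centring and -0.31, -0.36 and -0.37 on the values as deposited. Gimap4, Gimap6 and Gimap8 (-0.63, adjusted p = 0.00946) fell in LSEC, Gimap4 in lung endothelial cells and Gimap6 in thymus. The family was chosen because Gimap4 and Gimap6 fell. Of the 6 other members, 5, 4 and 6 stood below 0, with medians of -0.14, -0.20 and -0.32 (camera unadjusted p = 0.0633, 0.0499 and 0.00197, and p = 0.171, 0.151 and 0.0367 with an estimated correlation). The T cell marker list had medians of -0.06 in LSEC, -0.06 in lung endothelial cells and 0.02 in thymus.

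Among class 3 semaphorins, secreted guidance cues of vessels and axons, Sema3d fell by 3.16 in LSEC and Sema3g rose by 0.97, and the 6 tested members had a median of -0.08 there (camera unadjusted p = 0.209).

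Cap1, Usp24 and Plpp3 had effects of the same sign in all 3 tissues and lie on 1 chromosome. A chromosome segment of another strain, carried along with the Cre transgene, is a possible explanation. The floxed genes, Gm34303 and genes without a known chromosome were left out of the test. Of the rest, 39, 10 and 4 had effects of 1 sign with an absolute t of at least 2, 3 and 4 in every tissue. At most 6, 3 and 3 of them lay on 1 chromosome, and that of Cap1 held 5, 3 and 3. For the largest number on any chromosome, 10000 shuffles gave permutation p of 0.406, 0.265 and 0.0121. The answer changed with the limit on t, so the test decides nothing, and the arrays carry no genotypes.

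Tpsab1, Cpa3 and Hdc, which mast cells express, were among the largest rises in Cre+ LSEC, and more mast cells or basophils in these samples may be the source. Apart from these and Kit, the other mast cell genes tested numbered 4, with a median of 0.18. Of these, 3 stood above 0 and none passed. Camera gave that set a p of 0.197, which leaves the hypothesis open. Kit, a mast cell receptor gene that sinusoidal endothelium also expresses, was left out of that test and fell by 1.17. With all 8 tested genes of the list the median was 0.35 (camera p = 0.00961, and p = 0.103 with an estimated correlation). The log2 levels of Tpsab1 were 5.39 ± 0.64 in control and 8.89 ± 1.51 in Cre+ LSEC (SD, n = 3 each), so the Cre+ arrays differed widely among themselves.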
